A study of Mus musculus with 18 samples.

How the data were processed

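Small RNA was sequenced from sperm of male ICR mice, an outbred strain. Per the labels, the 18 libraries form 6 groups of 3 replicates: a control group (Con) and a group of the exposed line (NHS) in each of 3 generations, F0, F1 and F2. F0 NHS males were treated with ammonia and hydrogen sulphide for 5 weeks from 3 weeks of age and were then mated with untreated females. Their F1 sons received no treatment and were mated at 8 weeks of age, and the F2 males received none either. Nothing in the labels says that the replicates of a group are separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

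The authors deposited 1 table with a list of small RNAs per library, each entry with a count and a TPM value per the file headers. The deposited counts are whole numbers of reads. The deposited TPM values are the count divided by the total of the library, times 1000000, with no length term (tags per 1000000 reads). This was checked in the values and held for 100% of the entries of every library. In the 13 libraries with complete lists the total was the sum of the listed counts. In the others it came from the ratio of count to TPM, so there the check shows only that TPM is proportional to count. The submitters' processing notes name genome build mm10. The aligner, the counting tool, the filters and the tools that predicted miRNAs and piRNAs are not given in the sources used here. Further deposited tables give the positions of 6919 predicted miRNA precursors and the sequence and repeat class of the predicted piRNAs. Starts of the predicted precursors are counted from 0: 396 precursors inside transcripts of 1 exon matched the transcript sequence with that reading and 0 with starts counted from 1.

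The table ends after 96,730 lines, and the lists of 5 libraries reach its last line before their own end. F1 NHS replicates 1 and 3 list 2.17% and 1.74% of their reads, F1 NHS replicate 2 lists 42.3%, and F2 NHS replicates 2 and 3 list 35.8% and 40.3%. The other 13 lists hold 100% of their reads. Library totals, taken from the ratio of count to TPM where a list stops early, ranged from 17,224,394 to 29,430,555 reads. An entry at 1 TPM thus rests on at least 17.2 reads. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

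Each class of small RNA was tested in the libraries whose lists hold it whole. Predicted miRNAs were complete in 18 libraries. Known miRNAs were complete in 16, with replicate 2 as the sole F1 NHS library. Known piRNAs were complete in 13 libraries. For F1, F2 and the tests over generations, 2861 early-listed piRNAs were used in 16 libraries, since these come before the end of the shortest partial list. They are 7.9% of the piRNAs listed in any of the 16 libraries, and the 13 complete lists hold 35,824. Place in the list and mean count had a Spearman rho of -0.008 over the 9460 piRNAs listed in all 13 complete lists. Predicted piRNAs were used up to number 605324, where all 18 lists are complete, which covers 74.2% to 77.5% of the entries of the 16 complete lists. Rfam families, the deposited class of other structural RNA, were complete in 13 libraries, with 1 F2 NHS library and no F1 NHS library. Their F1 comparison, their mean over generations and their difference between generations were therefore not analysed here.

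Counts were fitted with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test, group means in 1 model per class) under R 4.3.3. Small RNAs with at least 1 CPM in at least 3 libraries were kept. Tests were two-sided, Benjamini-Hochberg adjustment ran within each class and contrast, and the threshold was 0.05. Contrasts were NHS against Con in each generation, the mean NHS effect over generations, the difference of the NHS effect between generations, and the differences between the 3 Con groups. DESeq2 1.42.0 was run beside it. A lone F1 NHS library was assumed to vary like the other groups. Where a group had no reads, a fold is given against a floor of 3 counts in each library. The smallest two-sided exact p of 3 against 3 libraries is 0.1 and that of 1 against 3 is 0.25. Tests of shares and of sequence numbers used exact permutation of the group labels, within generations where several were pooled (scipy 1.17.1).

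Gene lists were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 and, beside it, an estimated one. The 20 lists were the miR-34 and miR-449 family, the X-linked testis cluster, let-7, miR-30, miR-17-92 with its paralogs, miR-290-295 with miR-302, the Dlk1-Dio3 and Sfmbt2 clusters, epithelial miRNAs, epididymis-enriched miRNAs, stromal and smooth muscle, red blood cell, leukocyte, endothelial, skeletal and cardiac muscle, and liver miRNAs, a paternal stress list, a hypoxia and oxidative stress list, the miR-29 family, and sperm-abundant miRNAs relevant to oocyte and zygote. Of these, 19 had at least 3 measured members. All members came from general knowledge, not from these libraries. Lists share members: 3 of 12 epithelial, 3 of 7 miR-30, 4 of 8 miR-34 and miR-449, 9 of 16 hypoxia, 8 of 13 oocyte and zygote and 7 of 13 paternal stress members also stand in another list. The lists, the groups, the contrasts, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined. 1 called predicted miRNA is not reported here. The rule named called features that did not overlap between groups and reached 10 TPM, the 5 miRNAs with the smallest p where fewer passed, the 10 most abundant miRNAs, and up to 4 members of each list.

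Alternatives fixed beforehand were library totals as deposited, DESeq2 size factors and a fixed class total in place of TMM, no filter and a filter at 10 CPM, DESeq2, the libraries of 1 generation alone, the replicate number as a block, an estimated correlation, and leaving out each library in turn. The list tests and fold-change correlations were also to be run with a pseudocount of 10. Other pseudocounts were planned only for the case of normalised values and were not run, because counts are deposited. Alternatives chosen after seeing the data were limma on log2(TPM + 1), summing the 2 arms of each precursor, other choices of the piRNAs and predicted loci used, a term for 2 sets of libraries that the data show, and leaving out the smaller set. Scaling moved the median log2 fold change of a class by up to 0.54 for miRNAs (F1, library totals), -0.86 for piRNAs (F0, fixed total), 0.34 for Rfam families (F2, fixed total), 0.78 for predicted miRNAs (F0, fixed total) and -0.64 for predicted piRNAs (F2, library totals). Fold changes are relative to TMM. List medians were also computed under each scaling, chosen after seeing the data.

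The fit was tested on simulated data built from the F0 libraries and fitted to those alone. The reported fits share 1 spread over 16 libraries for miRNAs and 13 for piRNAs in F0, so their own sensitivity was not simulated. With 50 miRNAs changed per fold, 0%, 2%, 16% and 46% of 2-, 4-, 8- and 16-fold changes were called, and 0 of 32 calls were of unchanged miRNAs. For piRNAs the shares were 2%, 16%, 72% and 92%, and 2 of 93 calls were of unchanged piRNAs. Replicate numbers paired no libraries: 2 of 6 pairs of miRNA fold changes and 2 of 9 of predicted miRNA fold changes correlated above 0.1.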

Results

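Small RNA reads were measured in sperm of ICR mice in 6 groups of 3 libraries: control (Con) and exposed line (NHS) males of generations F0, F1 and F2. F0 NHS males received ammonia and hydrogen sulphide, 2 irritant gases of livestock buildings, and F1 and F2 NHS males were their untreated descendants. Library totals ranged from 17,224,394 to 29,430,555 reads. Lists that end early left 1 F1 NHS library, replicate 2, for known miRNAs, while F0 and F2 had 3 libraries per group. Values are tags per 1000000 reads (TPM), mean ± SD, and log2 fold changes are NHS over Con with their SE.

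The F0 comparison asks what direct exposure of the father does to sperm small RNA. Sperm of both F0 groups was rich in miR-143-3p, a smooth muscle miRNA, at 90,780 ± 54,860 TPM in Con and 76,490 ± 30,840 in NHS (n = 3 each). miR-451a, a red blood cell miRNA, stood at 51,810 ± 36,430 and 26,010 ± 8267. miR-34b-3p of the miR-34 and miR-449 family, which acts in multiciliated cells and in meiotic and haploid germ cells, stood at 2825 ± 1023 TPM in Con and 7159 ± 4494 in NHS (log2 fold change 1.52, SE 0.66). Its partner miR-34c-3p stood at 2016 ± 846 and 4709 ± 1693 (1.35, SE 0.59). For the differentiation-linked let-7 family, let-7a-5p was at 4249 ± 3708 and 280 ± 125 TPM (-3.66, SE 1.47) and let-7g-5p at 8669 ± 5506 and 2364 ± 167 (-1.77, SE 0.74). With both arms summed let-7a stood at 13,010 ± 8319 and 9242 ± 1732 TPM (-0.38, SE 0.44) and let-7g at 10,660 ± 4835 and 4953 ± 1241 (-1.11, SE 0.50). None of these differences passed the adjusted test.

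Of 735 miRNAs in F0, edgeR called 0, with 45 at an unadjusted p under 0.05 and a smallest adjusted p of 0.706. DESeq2 called 1, miR-5121, which was lower in NHS (187 ± 181 against 22.6 ± 22.7 TPM, -3.20, SE 0.86, DESeq2 adjusted p = 0.0225). The other miRNAs with the smallest p were miR-669d-2-3p (3.22, SE 0.91), miR-1291 (-3.26, SE 0.93), miR-15b-3p (1501 ± 683 against 262 ± 170 TPM, -2.48, SE 0.83) and miR-5100 (9.11 ± 3.22 against 79.3 ± 69.6 TPM, 3.33, SE 1.12), each with an edgeR adjusted p of 0.706.

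Among the miRNA lists in F0, 0 of 19 were called by camera. The let-7 family came closest: 7 of 9 measured members were lower in NHS, with a median log2 fold change of -1.16 (adjusted p = 0.0712). The miR-30 family (5 of 7 lower), skeletal and cardiac muscle miRNAs (5 of 5 lower) and the fibrosis-linked miR-29 family (5 of 5 lower) each had an adjusted p of 0.118. The hypoxia and oxidative stress list (11 of 15 lower) had 0.166 and the oocyte and zygote list (10 of 13 higher) 0.237. The miR-34 and miR-449 family (4 of 6 higher, median 1.14) and the imprinted Dlk1-Dio3 cluster (26 of 42 higher) had 0.397. The miR-290-295 with miR-302 list, of embryonic stem cells, and the epithelial list had 0.418. Red blood cell and leukocyte miRNAs had 0.72. The X-linked testis cluster, miR-17-92, epididymis-enriched, liver and paternal stress lists had 0.841, and the Sfmbt2 cluster and stromal miRNAs 0.862. The mean, median or test differed in sign for the Sfmbt2, leukocyte, liver and paternal stress lists. Adjusted over the list alone, 0 members were called in any list. Endothelial miRNAs, with 2 members, were not tested and took 0.668% of miRNA reads in F0 Con and 0.536% in F0 NHS.

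Predicted miRNA loci are sites that the submitters' tools scored as hairpins. Of 299 tested in F0, 4 fell in NHS and 0 rose (edgeR; 19 at an unadjusted p under 0.05, 6 called by DESeq2). novel_mir4212 lies on chromosome 7 at 109865617 to 109865693 (mm10, minus strand) in a UTR exon of Scube2, a secreted protein of hedgehog signalling. It fell from 59.8 ± 43.5 to 1.71 ± 0.96 TPM (-5.72, SE 1.07, adjusted p = 0.0107, all 3 NHS libraries below all 3 Con libraries). novel_mir6, on chromosome 13 at 44749631 to 44749711 on the strand opposite an intron of the chromatin regulator gene Jarid2, fell from 318 ± 352 to 15.9 ± 2.18 TPM (-5.21, SE 1.05, adjusted p = 0.0130). novel_mir5550, on chromosome 11 at 117077243 to 117077326 in an exon shared by the small Cajal body RNA gene Gm26083 and Snhg20, fell from 19.8 ± 16.3 to 0.502 ± 0.386 TPM (-5.12, SE 1.20, adjusted p = 0.0397). novel_mir4375, named after its values were seen, stood at 5.96 and 0.0566 TPM (adjusted p = 0.0397, and 0.46 with DESeq2). All 4 loci also differed between the unexposed Con groups of the 3 generations, tested with edgeR after the data were seen. The adjusted p was 0.000115 for novel_mir4212, 0.00961 for novel_mir6 and 0.00192 for novel_mir5550 and novel_mir4375. The falls are relative to F0 Con alone. Without F0 NHS replicate 1 or 2 each of the 4 calls was lost, and novel_mir6 was also lost without F0 Con replicate 2, novel_mir5550 without F0 Con replicate 1 or 3, and novel_mir4375 without F0 NHS replicate 3. Adjusted p over libraries left out ranged from 0.000481 to 0.115 for novel_mir4212, from 0.00484 to 0.139 for novel_mir6, from 0.0139 to 0.265 for novel_mir5550 and from 0.019 to 0.265 for novel_mir4375. All 4 calls were also lost with a fixed total within the class and with replicate numbers as a block, novel_mir4212 and novel_mir4375 with library totals in place of TMM, and novel_mir6 and novel_mir5550 with only the F0 libraries. Adjusted p under such other settings reached 0.27 for novel_mir4212 and novel_mir5550, 0.895 for novel_mir6 and 0.46 for novel_mir4375.

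**Figure D1:**
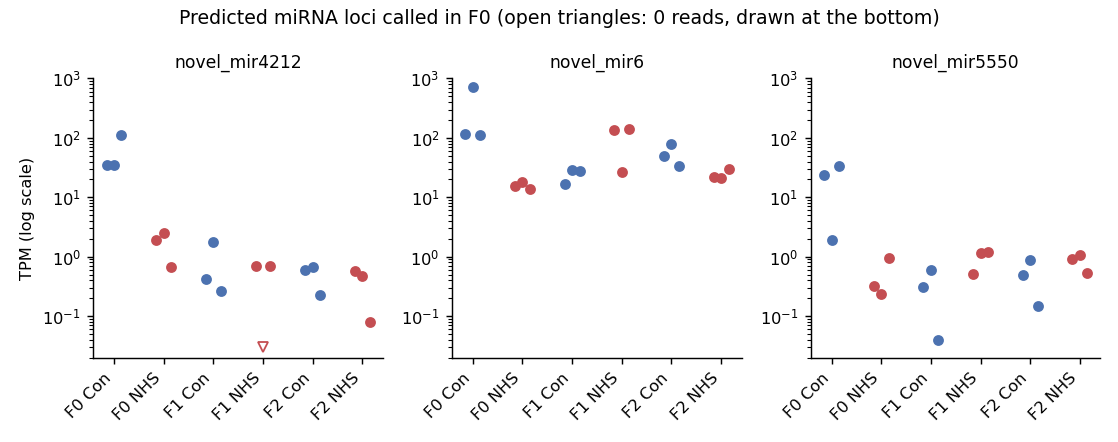
TPM (log scale) of 3 predicted miRNA loci in each of the 18 libraries, with open triangles for 0 reads. novel_mir4212, novel_mir6 and novel_mir5550 were lower in all 3 F0 NHS libraries than in the F0 Con libraries.

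Among known piRNAs, small RNAs that silence transposons in the male germline, edgeR called 0 of 6463 in F0 (503 at an unadjusted p under 0.05, 26 called by DESeq2, smallest adjusted p 0.188). As a class they took 3.97% ± 1.35 of reads in F0 Con and 8.77% ± 3.08 in F0 NHS (n = 3 each, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Their share was 8.35% in F1 Con and 8.45% in F2 Con. miRNAs took 49.9% ± 8.56 and 43.6% ± 8.29. Pooled over the generations with complete lists, 0 of 10 classes of small RNA differed between NHS and Con after adjustment (exact permutation, smallest adjusted p 0.542). For piRNAs, Rfam families and intron, exon, repeat and intergenic reads this pooled F0 and F2 alone, with 80 relabellings. So few relabellings cannot bring 1 such class alone past the adjusted threshold, so the count says little about these classes. Of 231 Rfam families, edgeR called 0 in F0 (46 at an unadjusted p under 0.05) and DESeq2 27. RF01960 stood at 5179 ± 1157 TPM in Con and 949 ± 55.8 in NHS (-2.35, SE 0.68) and RF00023 at 2226 ± 1280 and 15,180 ± 10,500 TPM (2.76, SE 0.83), each with an adjusted p of 0.0864. Families are given by ID only, and whether their reads come from mouse sperm RNA was not tested. For RF00023 the groups overlapped, with F0 NHS replicate 3 at 3090 TPM and F0 Con replicate 3 at 3700. The smaller set of libraries described with the tRNA reads holds F0 Con replicate 2 and F0 NHS replicate 3 among others. Leaving out that whole set left 2 F0 libraries per group, without the F0 NHS library that overlapped for RF00023. It gave 31 calls of 213 families, 10 higher and 21 lower, and an adjusted p of 0.0468 for both families. Without F0 NHS replicate 3 alone 21 were called. Of 937 predicted piRNAs, edgeR called 0 in F0 (43 at an unadjusted p under 0.05, 13 by DESeq2).

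The F1 comparison asks whether untreated sons of exposed males differ. In the lone F1 NHS library miR-204-3p, from an intron of Trpm3, stood at 3.14 TPM against 123 ± 150 in F1 Con (-5.55, SE 1.47). miR-196b-3p of the Hox clusters stood at 1627 against 123 ± 54.6 (3.10, SE 0.95), miR-99a-3p at 4354 against 319 ± 153 (3.13, SE 1.0) and the erythroid miR-486b-5p at 5.18 against 163 ± 75.3 (-5.61, SE 1.88). With both arms summed these gaps were smaller: miR-204 stood at 40.5 against 181 ± 143 TPM (-2.48, SE 0.99), miR-196b at 2865 against 933 ± 475 (1.26, SE 0.61), miR-99a at 10,400 against 4206 ± 984 (0.85, SE 0.56) and miR-486b at 83.6 against 487 ± 387 (-3.11, SE 1.09). The lone F1 NHS library belongs to the smaller set described with the tRNA reads and all 3 F1 Con libraries to the larger, so within F1 set and exposure cannot be told apart. edgeR called 0 of 735 miRNAs (44 at an unadjusted p under 0.05, smallest adjusted p 0.745) and DESeq2 7, all lower in NHS, among them miR-204-3p (adjusted p = 4.61e-05). miR-210-5p, with the smallest p besides, had 0 reads against 1.14 TPM in Con, at least 11-fold lower. Of 19 lists 0 were called, with adjusted p of 0.919 or more. miR-34 and miR-449, epithelial, epididymis-enriched, liver and hypoxia lists had a median, mean or test of different sign, and adjusted over the list alone 1 hypoxia member was called. With the arms of each precursor summed, an alternative chosen after seeing the data, the let-7 and miR-17-92 lists were higher (adjusted p = 0.0469 for each, and adjusted p = 0.854 with an estimated correlation), while the miR-17-92 share of miRNA reads was 1.68% ± 0.219 in F1 Con and 1.63% in the F1 NHS library. Of 580 early-listed piRNAs edgeR called 0 (28 at an unadjusted p under 0.05, 4 by DESeq2, smallest adjusted p 0.0992). With all 6 F1 libraries, edgeR called 0 of 299 predicted miRNAs (26 at an unadjusted p under 0.05, 3 by DESeq2) and 0 of 937 predicted piRNAs (63 and 8).

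The F2 comparison asks the same of untreated grandsons. Epithelial miRNAs, of the miR-200, miR-141, miR-205 and miR-183 families that keep epithelial identity and are abundant in epididymis, rose as a list: 11 of 12 members were higher in F2 NHS, with a median log2 fold change of 1.33 (adjusted p = 0.00568; adjusted p = 0.216 with an estimated correlation). miR-200c-3p stood at 2620 ± 352 TPM in Con and 9276 ± 3107 in NHS (1.60, SE 0.53), miR-200b-3p at 386 ± 74.7 and 1889 ± 943 (2.05, SE 0.64), and miR-182-5p at 87.4 ± 82.5 and 775 ± 606 (2.92, SE 1.0), or with both arms of miR-182 at 405 ± 266 and 967 ± 645 (0.93, SE 0.64). With the arms of each precursor summed, an alternative chosen after seeing the data, the epithelial median was smaller, at 0.77. Its camera adjusted p was 0.018, and 0.353 with an estimated correlation. Both arms together, the list took 3.52% ± 0.0197 of miRNA reads in F2 Con and 6.18% ± 0.980 in F2 NHS, with no overlap of 3 against 3 libraries, which chance gives in 10% of splits. F2 Con was the lowest group, with 5.5% in F0 Con and 4.7% in F1 Con. The miR-30 family, which restrains the autophagy gene Becn1, rose as a list, with 7 of 7 members higher (median 1.62, adjusted p = 0.0463; adjusted p = 0.54 with an estimated correlation). miR-30a-5p stood at 47.6 ± 27.0 and 462 ± 301 TPM (2.91, SE 0.87), and both arms of miR-30a at 412 ± 136 and 1217 ± 569 (1.22, SE 0.44). Both arms together, the miR-30 list took 1.62% ± 0.492 of miRNA reads in F2 Con and 2.43% ± 1.03 in F2 NHS, and the libraries overlapped.

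Without each F2 library singly, the epithelial median ranged from 1.11 to 1.74, with 10 to 12 of 12 members higher, and the call was lost without F2 Con replicate 3 (adjusted p = 0.0703, median 1.25). The miR-30 call was lost without F2 NHS replicate 3 (adjusted p = 0.4, median 0.60), F2 Con replicate 2 (0.284, median 1.74) or F2 Con replicate 3 (0.248, median 1.70), on leaving out singly each F0 or F1 library except F0 Con replicate 1 (0.0505 to 0.0718), and with a term for the 2 sets of libraries (0.0612), where the epithelial list had 0.0105. Adjusted over the list alone, 3 epithelial members were called, 2 of the paternal stress list and 1 each of the let-7, miR-30, miR-17-92, stromal, red blood cell and liver lists.

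In the opposite direction from the epithelial list in F2, miR-34b-3p stood at 13,520 ± 3276 TPM in Con and 5197 ± 825 in NHS (-1.62, SE 0.67). The miR-34 and miR-449 family as a list had an adjusted p of 0.225 (3 of 6 lower), with 8.66% ± 2.61 of miRNA reads in F2 Con and 3.44% ± 0.533 in F2 NHS, both arms, without overlap. The same adjusted p held for the X-linked testis cluster (24 of 34 lower), the oocyte and zygote list (7 of 13 lower), miR-17-92 (11 of 12 higher), red blood cell (5 of 6 higher), muscle (4 of 5 higher) and liver miRNAs (3 of 4 higher). Stromal miRNAs (7 of 9 higher) had 0.243, the paternal stress list 0.403, hypoxia 0.637, let-7, miR-290-295 with miR-302 and Sfmbt2 0.783, the epididymis-enriched list 0.825, and Dlk1-Dio3, leukocyte and miR-29 lists 0.868. Dlk1-Dio3 and miR-29 had a median, mean or test of different sign. With arms summed the miR-17-92 list was higher (adjusted p = 0.0277, and adjusted p = 0.447 with an estimated correlation) and miR-30 had 0.0619. The share of miRNA reads of the miR-17-92 list was not higher, at 1.01% ± 0.278 in F2 Con and 0.942% ± 0.0845 in F2 NHS with both arms, and at 0.841% ± 0.163 and 0.555% ± 0.0773 over the listed arms, without overlap.

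**Figure D2:**
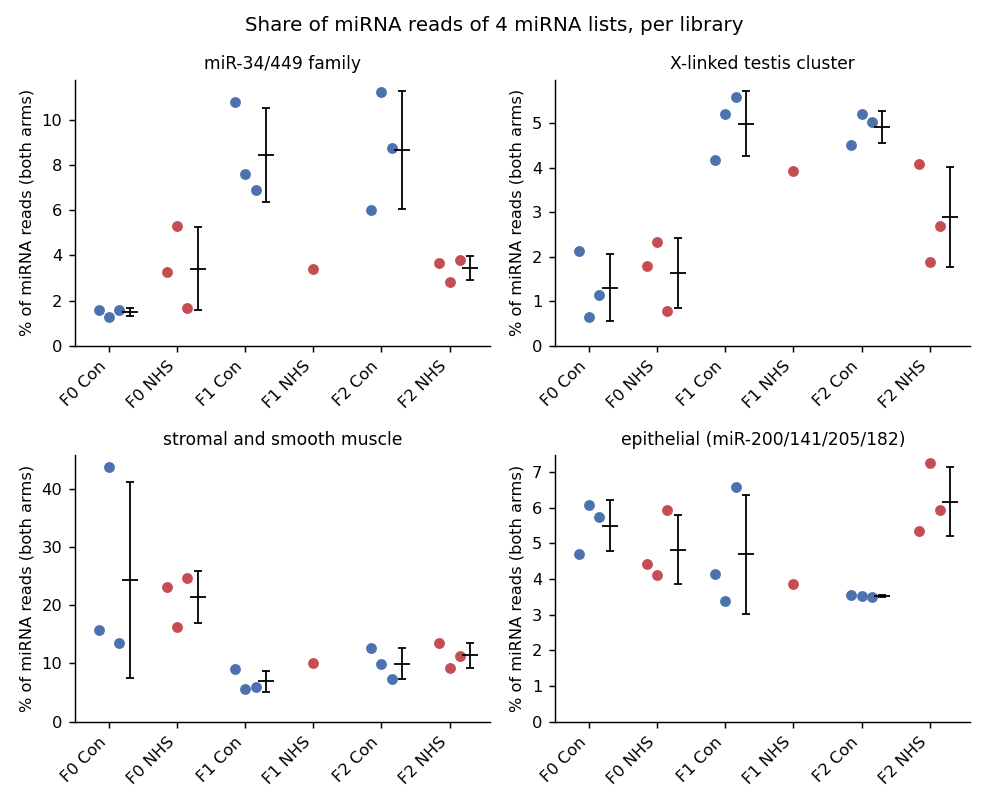
Percent of miRNA reads, both arms of each precursor, in each library for the miR-34 and miR-449, X-linked, stromal and epithelial lists, with bars for mean ± SD, Con in blue and NHS in red. The miR-34 and miR-449 share was 1.49% in F0 Con, 8.43% in F1 Con and 8.66% in F2 Con, and F1 NHS has 1 library.

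Single miRNAs in F2 gave 0 calls of 735 in edgeR, 80 at an unadjusted p under 0.05 and 30 in DESeq2. Those with the smallest p were miR-19a-3p, of the growth-promoting miR-17-92 cluster (1.57 ± 0.412 against 18.03 ± 14.1 TPM, 3.21, SE 0.73), miR-361-5p (5.31 ± 0.643 against 38.1 ± 22.3, 2.59, SE 0.63), miR-362-3p (0.863 ± 0.666 against 7.38 ± 2.94, 2.88, SE 0.70) and miR-143-5p, with 0 reads in F2 Con and at least 38-fold higher in NHS (edgeR adjusted p = 0.184 for each), then miR-6239 (-2.55, SE 0.67, adjusted p = 0.256). miR-26a-5p was at 680 ± 129 and 13,660 ± 9808 TPM (4.13, SE 1.38), but both arms of its precursor together at 11,170 and 20,820 TPM.

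Of 299 predicted miRNAs, 1 rose in F2 NHS (44 at an unadjusted p under 0.05, 4 by DESeq2). Of 937 predicted piRNAs, 1 rose (96 at an unadjusted p under 0.05, 43 by DESeq2): novel_pir295434, CAAATCCCGGACGAGCCCCCA, listed under ERV1 repeats by the submitters' annotation, with 0 reads in F2 Con and 3.76 ± 2.0 TPM in NHS, at least 27.8-fold higher (adjusted p = 0.0294, named after its values were seen). That call was lost on leaving out 9 of 18 libraries singly (adjusted p 0.0192 to 0.209), and under 5 of 11 other settings: all predicted piRNAs, limma, no filter, only the F2 libraries and the replicate block (up to 0.987). edgeR called 0 of 580 early-listed piRNAs (87 at an unadjusted p under 0.05, 16 by DESeq2) and 0 of 231 Rfam families (10 and 1).

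The mean NHS effect and its difference between generations ask whether an exposure effect is shared or passed on. Over F0, F1 and F2, edgeR called 0 of 735 miRNAs for the mean (57 at an unadjusted p under 0.05, 12 by DESeq2), with miR-204-3p (-2.59, SE 0.60) and miR-19a-3p (1.67, SE 0.43) at an adjusted p of 0.377. The 19 lists had adjusted p of 0.656 or more; let-7, X-linked, miR-17-92, epididymis, miR-29 and paternal stress differed in sign between median, mean or test. Summed arms gave miR-17-92 higher (adjusted p = 0.00583, and adjusted p = 0.928 with an estimated correlation). For the difference between generations edgeR called 0 miRNAs (71 at an unadjusted p under 0.05, 11 by DESeq2) and 1 piRNA, mmu_piR_039256 (adjusted p = 0.037). miRNA fold changes of F0 and F2 had r = -0.22 and rho = -0.21 across 735 miRNAs, which are not independent replicates (permutation p 0.0891 and 0.0693, 100 relabellings), and r ranged from -0.236 to -0.117 without each library singly, the last without F2 NHS replicate 3. F0 with F1 gave r = 0.01 (p = 0.921) and F1 with F2 r = 0.02 (p = 0.941). Of 299 predicted miRNAs, tested for the mean after the data were seen, 2 were called, of which 1 is not reported here and the other is novel_mir4212 (-2.41, SE 0.54, adjusted p = 0.0439), whose log2 fold change was -5.72 in F0, -0.89 in F1 and -0.60 in F2.

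The Con groups show what differs between generations without exposure, where age, mating and batch may also differ. miR-34b, both arms, was at 2892 ± 1025 TPM in F0 Con, 8328 ± 1193 in F1 Con and 13,570 ± 3292 in F2 Con (log2 differences from F0 2.55 and 2.93, adjusted p = 0.0105). miR-34c was at 2037 ± 839, 5300 ± 1601 and 6608 ± 1826 (adjusted p = 0.0105). miR-143 fell from 90,780 to 8985 ± 3359 and 17,060 ± 9249 (adjusted p = 0.0181), miR-200b from 3035 ± 918 to 409 ± 178 and 394 ± 77.5 (0.0165) and miR-29c from 450 ± 68.8 to 45.7 ± 12.9 and 59.6 ± 9.33 (0.0181). With arms summed, chosen after seeing the data, 45 of 461 precursors were called (151 at an unadjusted p under 0.05): 22 lower in F1 and F2, 18 higher in both and 5 in opposite directions. With arms apart edgeR called 0 of 735 (143 at an unadjusted p under 0.05, 86 by DESeq2, smallest adjusted p 0.0706).

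Lists moved between Con generations too, relative to the other miRNAs. In F1 Con over F0 Con the miR-34 and miR-449 family (6 of 6, median 2.43, adjusted p = 0.0088) and X-linked testis cluster (27 of 34, 0.87, 0.000422) rose, and stromal (8 of 9 lower, -2.38, 0.0088), miR-29 (5 of 5 lower, -1.19, 0.0088) and Dlk1-Dio3 miRNAs (35 of 42 lower, -0.73, 0.000422) fell (adjusted p = 0.2 for each with an estimated correlation). The summed reads of Dlk1-Dio3 went the other way than its typical member, at 0.738% ± 0.0962 of miRNA reads in F0 Con and 1.12% ± 0.0973 in F1 Con, both arms, with no overlap. miRNAs as a class took 49.9% ± 8.56 of reads in F0 Con, 21.1% ± 10.2 in F1 Con and 27.4% ± 6.33 in F2 Con. Scaled to library totals, the median of all miRNAs moved to -0.88 in F1 Con over F0 Con and to -0.54 in F2 Con, and the X-linked median in F1 Con turned to -0.13, while the other 4 lists kept their sign under each scaling. In F2 Con over F0 Con the X-linked cluster rose (24 of 34, 0.75, 0.0275), and the epithelial (10 of 12 lower, -0.89, 0.0384) and miR-29 lists (5 of 5 lower, -1.37, 0.0303) fell (adjusted p = 0.333 for each with an estimated correlation). Of 6463 piRNAs 7 were called, all lower in F1 and F2 (961 at an unadjusted p under 0.05, 220 by DESeq2), among them mmu_piR_000219 (82.8 ± 29.1, 14.8 and 6.34 TPM) and mmu_piR_000619 (119 ± 57.7, 10.9 and 11.2 TPM). The count was 0 without F0 Con replicate 1, F0 Con replicate 2 or F2 Con replicate 3 and 10 without F2 Con replicate 2. Of 231 Rfam families 22 were called (71 at an unadjusted p under 0.05, 64 by DESeq2), with RF01677 (adjusted p = 0.00216) and RF01960 (5179, 1287 and 1757 TPM, adjusted p = 0.0272); the count was 1 without F0 Con replicate 1 and 50 without F0 NHS replicate 3.

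Reads of tRNA origin split the libraries into 2 sets that cross the groups unevenly, the smaller with 0 of 3 F1 Con and 2 of 3 F2 Con libraries. The predicted locus novel_mir1, in a tRNA-Ala gene, held 2378 to 18,720 TPM in 6 libraries (F0 Con 2, F0 NHS 3, F1 NHS 2, F2 Con 1, F2 Con 2 and F2 NHS 1) and 42.9 to 621 TPM in the other 12. Family RF00005 ran the other way, at 43.2 to 659 TPM in 5 libraries of the smaller set and 3542 to 20,400 TPM in 8 of the larger. Of the reads at the 6919 predicted loci, pooled over libraries, 67.7% lay at 5 loci in tRNA genes and 11.4% at 3 loci in rRNA genes. The 5 tRNA loci held 70,910 TPM in F0 Con 2, 3282 to 20,610 in the rest of the smaller set and 389 to 2149 in the larger.

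**Figure D3:**
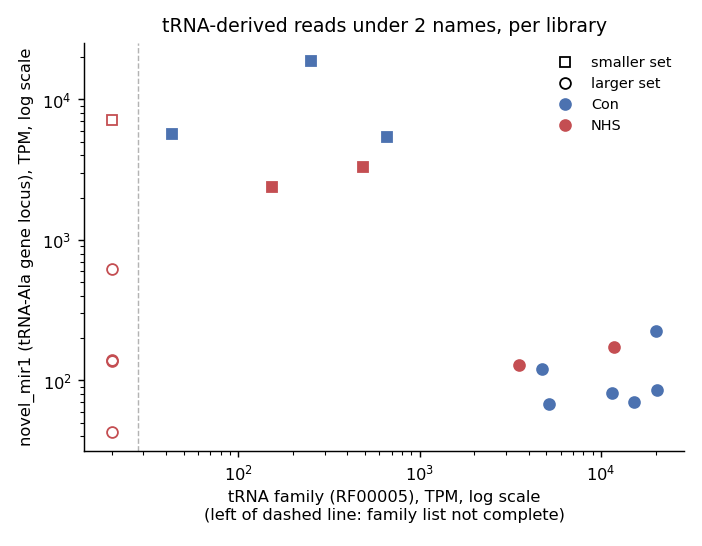
TPM of family RF00005 against TPM of novel_mir1 in each library, both on log scales, squares for the smaller set and circles for the larger. Open symbols left of the dashed line are libraries whose family list is not complete.

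Sequences that the submitters' tools listed as predicted piRNAs were counted in each library. Of 601,270 such sequences, 28.1% had at least 24 nt, the median length was 21 nt, 33.2% began with U and 59.6% were seen with 1 read in all libraries, so most were shorter than piRNAs and most did not begin with U. Each F1 NHS library held more distinct sequences than each F1 Con library (75,680 ± 16,990 against 37,810 ± 5111, exact permutation p = 0.1), as did each F2 NHS library over F2 Con (54,800 ± 17,770 against 25,930 ± 4348, exact permutation p = 0.1). F0 NHS held 40,800 ± 5596 and F0 Con 46,260 ± 3214 (exact permutation p = 0.2). Stratified over 3 generations the exact permutation p was 0.013, or 0.26 adjusted over the 20 relations computed, which does not pass. Within the larger set F1 NHS held 75,143 to 92,941 and F1 Con 31,962 to 41,438 sequences; within the smaller set F2 NHS held 34,306 and F2 Con 22,199 to 30,706.

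**Figure D4:**
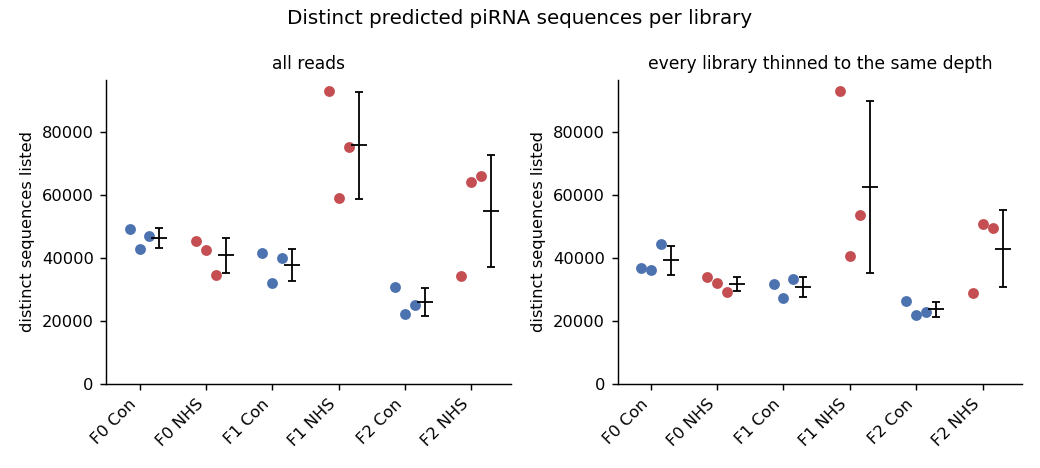
Distinct predicted piRNA sequences in each of the 18 libraries, from all reads and from libraries thinned to equal depth. F1 NHS and F2 NHS libraries lie above the Con libraries of their generation from all reads.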

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

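The tests of arm correlation, of the exposure in the predicted piRNAs, of the epithelial median without each library, of the 2 sets of libraries and of splits between Con generations were chosen after the results were seen.

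Epithelial miRNAs were higher in F2 NHS than in F2 Con, and their NHS effect differed between F2 and F0 (adjusted p = 0.0113 for the difference, and adjusted p = 0.237 with an estimated correlation). A term for the 2 sets of libraries left the list past the threshold (adjusted p = 0.0105), which argues against the sets as the whole cause, and 1 library as the source of its size is argued against because the median without each F2 library stayed at 1.11 or more (1.33 with all). Those medians are of arms as listed, and with arms summed the median with all libraries was 0.77. The call itself was lost without F2 Con replicate 3 (adjusted p = 0.0703, in a range from 0.00406), with the median at 1.25. A larger share of epididymal or other somatic cells beside sperm stays open. Germ-cell minus somatic lists, 22 precursors each, stood at -2.23 to -1.33 (log2) in F2 NHS and -0.35 to -0.33 in F2 Con. The difference was -1.30 (exact permutation p = 0.1, two-sided, n = 3 each), with p = 0.5 in F0. The somatic lists include the epithelial list, so this difference partly restates the rise and cannot decide its source. Other tissue lists were mixed in F2, by share of miRNA reads with both arms. Stromal, epididymis-enriched and liver lists overlapped, and leukocyte and endothelial means were lower in NHS. Red blood cell and muscle lists were higher in NHS without overlap. Within groups the germ-cell and somatic levels correlated at r = 0.30 (permutation p = 0.402, rho = 0.25, p = 0.448, 15 libraries), a spread too wide to decide. Without the 2 libraries farthest from the median r was 0.33. An effect of the grandfather's exposure cannot be told apart from a somatic source with 3 libraries per group. The difference is also relative to F2 Con, which had the lowest mean epithelial share of the 6 groups, both arms, while F2 NHS had the highest. Shares were 5.5%, 4.7% and 3.5% in F0, F1 and F2 Con, and 4.8%, 3.9% (1 library) and 6.2% in NHS. A low F2 Con group and a high F2 NHS group were not told apart.

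More distinct predicted piRNA sequences appeared in F1 and F2 NHS libraries. Depth as the whole cause is argued against, because libraries thinned to equal depth kept an F1 ratio of 2.03, without overlap. F1 NHS replicate 1 was the highest, at 92,941 sequences, and its depth set the level, so it was not thinned. At that depth F1 NHS replicates 2 and 3 held 40,529 and 53,655 sequences and the F1 Con libraries 27,063 to 33,235. An effect of the F0 exposure in the same direction in all 3 generations was not seen in F0. The F0 ratio at equal depth was 0.81, with every NHS library below every Con library (exact permutation p = 0.1, the smallest that 3 against 3 allows). From all reads the F0 groups overlapped (exact permutation p = 0.2), so F0 does not decide. An effect in F1 and F2 alone stays open: its exact stratified permutation p of 0.005 at equal depth is the smallest that 400 relabellings allow, and F1 and F2 were joined after their separation was seen, so it does not decide. Also open are short fragments of degraded RNA, as 2 of 3 F1 NHS libraries had a lower share of sequences of at least 24 nt than every F1 Con library, while in F2 the shares overlapped (28.1% to 40.2% in NHS, 23.4% to 48.4% in Con). Sequences seen with 1 read made up 69.7% to 79.5% of those in F1 NHS and 44.1% to 63.5% in F1 Con, but overlapped in F2 (38.6% to 67.8% in NHS, 18.1% to 45.3% in Con) and stood at 69.6% to 81.2% in F0 Con.

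Reads of many miRNAs moved between the 5p and the 3p name of the same precursor, as for let-7c, whose 5p share ranged from 0.959% to 89.1% between libraries. Over 139 precursors the arms correlated at a median of -0.153 within groups, against 0.0875 for arms of different precursors. A negative correlation is what reads of 1 mature miRNA counted under either name would give. The sum of both arms varied less than the larger arm in 92.1%. Arms that vary independently can also give a less variable sum, and no null was computed for this share, so it does not decide. Arm use that differs between the 6 groups stays open: groups explained a median share of variance of 0.285, and 8 of 100 relabellings gave as much, too near the bound set for that test to decide. No other biological explanation was tested.

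The miR-30 family also differed between F2 and F0 in its NHS effect (adjusted p = 0.0113, and adjusted p = 0.331 with an estimated correlation). The NHS effect on mmu_piR_039256 differed between generations (adjusted p = 0.037; log2 fold change 1.20 in F0, -5.80 in F1 and -2.51 in F2), at levels of 0.0690 to 3.19 TPM, and that call was lost on leaving out 12 of 15 libraries singly (adjusted p 0.00616 to 0.207) and under 5 of 8 other settings: fixed total, library totals, limma, replicate block and the term for the 2 sets (up to 0.321). The NHS effect on novel_mir6 differed between generations (adjusted p = 0.0359). Among 65 predicted siRNAs, a class outside the comparisons of the report, novel_sir5584 was higher in F2 NHS (log2 fold change 8.00, SE 1.69, adjusted p = 0.019) and differed between Con generations (adjusted p = 0.0175).

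Splits of the same 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For the 4 predicted miRNA calls in F0, 1 split gave as many and the highest other gave 0. For the 1 call in F2, 2 splits gave as many and the highest other gave 3, and for the 2 F2 list calls 2 splits and 3. With real counts of 0, all 10 splits give as many by construction, which says nothing of chance: the highest other was 0 for miRNAs in F0 and F2, piRNAs in F0, Rfam families in F0 and predicted piRNAs in F0 and F1, 1 for predicted miRNAs in F1, 2 for lists in F0 and 12 for piRNAs in F2. For the 1 predicted piRNA call in F2, 2 splits gave as many, and the split that puts F2 Con 1, F2 Con 2 and F2 NHS 1 together gave 305, which points to a structure of the samples that follows the tRNA reads. For the 5 and 3 lists called in F1 Con and F2 Con over F0 Con, 1 and 2 splits gave as many, with 3 and 4 as the highest other.

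For the 3 Con groups together, 100 of 280 possible splits were drawn. The 22 Rfam calls were reached by 1 split, the real one, with 10 as the highest other, and the 45 precursors with summed arms by 1 with 26 as the highest other. No other drawn split gave as many for either. This weighs against chance only if the libraries of a group are independent, which the labels do not say. The Rfam count was 1 without F0 Con replicate 1, and arms were summed after the planned miRNA test had given 0 calls. The 7 piRNA calls were reached by 7 of 100, up to 29, so chance is not excluded for these. A miRNA count of 0 is reached by all 100 by construction (highest other 1), so that count tests nothing.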

How the results depend on the processing

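Added after seeing the data were limma, summed arms, early-listed or all piRNAs, all predicted piRNAs, loci outside tRNA genes, log2(TPM + 1), the term for the 2 sets of libraries and leaving out the smaller set. Of 13,115 values under alternatives, 12,546 were classed as the same. These were features or lists that kept direction and side of the threshold, counts that changed little, and correlations that moved by less than their spread. A further 124 no longer passed or fell to a count of 0, and 192 newly passed. Another 253 moved, which includes changes of sign in features that passed in neither setting. Reversal, a change of sign in a feature or list that passed in either setting, was found for 0. Most of the 13,115 values belong to single features or lists, for which staying uncalled counts as the same. Among the values that answer a comparison, 525 of 590 were the same on leaving out 1 library. Under other settings fewer were: 130 of 196 planned values and 53 of 85 values chosen after seeing the data. Rfam families were not run where a group had no library, nor pseudocount changes meant for normalised values. Where an alternative changed a count below, the cause was not tested. The self-test, fitted to simulated F0 libraries alone with 3 per group, called 16% of 8-fold and 46% of 16-fold miRNA changes. Most changes of these sizes would be missed in such a fit. The reported miRNA fit shares 1 spread over 16 libraries (coefficient of variation 0.82). Its own sensitivity was not simulated, so missed changes remain possible. Known miRNAs in F1 rest on 1 NHS library, assumed to vary like the other groups. The class share count of 0 held under its alternatives. For piRNAs, Rfam families and intron, exon, repeat and intergenic reads a lone change could not have passed, so there it says little.

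With DESeq2 the calls were 1, 7 and 30 miRNAs in F0, F1 and F2, 12 for the mean, 11 for the difference between generations and 86 between Con generations. For piRNAs DESeq2 gave 26, 4, 16, 14, 5 and 220 in that order, for Rfam families 27 in F0, 1 in F2 and 64 between Con generations, for predicted miRNAs 3 in F1 and 4 in F2, and for predicted piRNAs 13, 8 and 43.

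With no filter on low counts the calls were 3 miRNAs in F2, 3 for the difference and 38 between Con generations. piRNAs gave 12, 2 and 20 in F0, F1 and F2, 12 for the difference and 349 between Con generations. Rfam families gave 15, 1 and 50 for F0, F2 and Con generations, predicted miRNAs 10, 45 and 5 and predicted piRNAs 9, 17 and 5 in F0, F1 and F2. With a filter of 10 CPM piRNAs gave 1 for the mean and 0 for the difference, Rfam families 12 between Con generations, predicted miRNAs 2 in F0 and 0 in F2, predicted piRNAs 0 in F2, and piRNA fold changes correlated at -0.282 for F0 with F1 and -0.055 for F1 with F2.

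With library totals as deposited there were 23 miRNAs between Con generations, 1 piRNA in F0, 0 for the piRNA difference and 2 predicted miRNAs in F0. With a fixed total within the class there were 1 piRNA in F0, 0 for the difference, 1 Rfam family in F2 and 43 between Con generations, and 0, 1 and 3 predicted miRNAs in F0, F1 and F2. With limma on log2(TPM + 1) there were 20 miRNAs between Con generations, 1 and 4 piRNAs in F0 and F1, 3 for the difference and 21 between Con generations, 1 Rfam family in F0 and 13 between Con generations, 1 and 0 predicted miRNAs in F1 and F2, and 1 and 0 predicted piRNAs in F0 and F2.

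Only the libraries of the generation gave 2 and 0 predicted miRNAs in F0 and F2 and 0 predicted piRNAs in F2. Replicate numbers do not pair the libraries; as a block they gave 0 predicted miRNAs in F0 and F2, 0 predicted piRNAs in F2, 0 for the piRNA difference and 1 list in F2. Early-listed piRNAs alone gave 0 between Con generations, and all predicted piRNAs gave 0 in F2. Arms summed gave 45 precursors between Con generations, 2 lists in F1 and 1 for the mean. F2 lists numbered 1 with log2(TPM + 10), 1 with log2(TPM + 1) and 0 with an estimated correlation.

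A term for the 2 sets of libraries gave 1 miRNA in F0, F1, the mean and Con generations, 0 for the piRNA difference, 1 and 5 predicted piRNAs in F0 and F2, and 1 list in F2. Leaving out the set of 6 libraries gave 31 Rfam families in F0, 2 piRNAs in F2 and 0 between Con generations, 25 predicted miRNAs in F2, and 2, 7 and 36 predicted piRNAs in F0, F1 and F2. Its F2 counts rest on 1 Con library, F2 Con replicate 3, assumed to vary like the other groups.

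Leaving out 1 library at a time gave 0 to 1 lists in F0 and 0 to 2 in F2, and 0 to 5 miRNAs between Con generations (5 without F0 NHS replicate 3). Rfam families ranged from 0 to 21 in F0 (21 without F0 NHS replicate 3), 0 to 1 in F2 and 1 to 50 between Con generations (1 without F0 Con replicate 1, 50 without F0 NHS replicate 3). piRNAs ranged from 0 to 1 in F1 and for the difference, 0 to 3 for the mean (3 without F1 Con replicate 1) and 0 to 10 between Con generations (10 without F2 Con replicate 2). Predicted miRNAs ranged from 0 to 4 in F0 (0 without F0 NHS replicate 1 or 2) and 1 to 3 in F2 (3 without F2 Con replicate 1), and predicted piRNAs from 0 to 3 in F2 (3 without F2 NHS replicate 1). Fold-change correlations ranged from -0.107 to 0.078 for miRNA F0 with F1 and from -0.172 to 0.047 for piRNA F0 with F2.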

Other observations

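The list totals and summed arms read here were chosen after the results were seen.

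Stromal and smooth muscle miRNAs took 24.4% ± 16.9 of miRNA reads in F0 Con (43.8% in replicate 2, 15.8% and 13.5% in the others), 6.91% ± 1.85 in F1 Con and 9.96% ± 2.69 in F2 Con, against 21.4% ± 4.44 in F0 NHS, 10.03% in the F1 NHS library and 11.4% ± 2.16 in F2 NHS. Red blood cell miRNAs took 11.4% ± 6.80, 13% ± 1.09 and 4.06% ± 1.01 in the Con groups, against 7.52% ± 1.30, 17.7% and 6.50% ± 1.82 in the NHS groups. The X-linked testis cluster, expressed in germ cells, took 1.31% ± 0.756, 4.99% ± 0.727 and 4.92% ± 0.354, against 1.64% ± 0.784, 3.94% and 2.89% ± 1.11 in NHS. miR-871, a member of that cluster, stood at 496 ± 377, 2031 ± 1421 and 1812 ± 470 TPM with arms summed (adjusted p = 0.0181).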
